A study of Mus musculus with 29 samples.

How the data were processed

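The deposited log2 values of 29 arrays were used as they were. According to the submitters' processing notes they were made with RMA in Expression Console 1.1, which corrects the background, equalises the quantiles of the arrays and gives 1 value per probe set. The notes state neither filters nor a genome build. Cells at passage 27 had received 50 nM of a mimic or of the control oligonucleotide for 36 h.

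Of 35556 probe sets, 21789 carried 1 gene symbol, 1621 several and 12146 no listed gene. Each gene was represented by the probe set with 1 symbol and the highest mean, which left 19938 genes, of which 999 had more than 1 probe set. Symbols of 21698 probe sets were checked through their Entrez identifiers, and 0 had to be changed. An older name in a gene list was followed to the current symbol only where the older name is not itself a current symbol. That rule was corrected after list results had been seen, because it had sent Gpi1 and Loxl2 to other genes. With the correction 73 pairs of a list and a microRNA passed, the call for glycolysis and hypoxia genes under miR-145 among them, which had not passed before.

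Each control array was averaged with the technical repeat of the same number, which gave 3 control values. The Pearson's r of an array with its own repeat was 0.996 for the 3 control transfections. For control replicate 2 the repeat numbered 3 correlated slightly better (0.9960 against 0.9959), and control replicates 2 and 3, which are separate transfections, had an r of 0.9966, above that of any array with its own repeat. By these correlations across probe sets the pairing of the repeats is uncertain, and they do not set repeats apart from separate transfections. With group means taken out, the labelled pairs had a consensus correlation of 0.607. That value was not computed for any other pairing. One linear model per gene was fitted in limma 3.58.1 (R 4.3.3) to 24 values in 8 groups, with group as the only term and with variances moderated along a trend with mean expression. Each microRNA was compared with the control, and in a second set of comparisons with the mean of the other 6 microRNAs. P values were adjusted by the Benjamini-Hochberg method within each comparison, with a threshold of 0.05, and limma's F test covered the 7 comparisons with the control together. All tests of genes and lists were 2-sided. No filter on dim genes was applied.

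Gene lists with at least 5 measured members, 33 in all, were compared with all other genes by limma's camera with a preset correlation of 0.01, adjusted over all 231 pairs of a list and a microRNA. A second adjusted p was computed with the correlation estimated for each list. Members that passed were counted once from the adjustment over all genes and once adjusted over the list alone. A member count near the share of all genes that passed under that microRNA is not in itself a sign of a list shift. Groups, models, gene lists and the rule for named genes were fixed before the data were examined. Named are, for each microRNA, the 8 largest decreases and the 5 largest increases among genes that passed and whose 3 values lay on 1 side of all 3 control values. Also named are up to 5 members of a list that passed, 10 genes in each direction called by the most microRNAs, and the 12 largest differences in each direction between myotube and myoblast among genes whose higher value exceeded the median of all genes. A planned test of genes with seed sites in their 3' untranslated regions was not run, because it needs transcript sequences, which were not used here.

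Whether replicate numbers pair the samples was checked on residuals. All 24 of 24 values correlated best with values of their own number, and the mean r was 0.240 for samples of the same number and −0.120 for others. The second mean is no separate evidence, because residuals sum to 0 within a group, which makes it negative where the first is positive. In 75 of 84 same-number pairs r exceeded 0.1. For miR-34a, miR-22, miR-365 and miR-29a all 3 pairs with the control exceeded 0.1, and for these the count with the replicate number as a block is given beside the count without it. The correlation of each list was estimated only in the model without this block. Variation shared by samples of the same number may therefore enter the adjusted p values with an estimated correlation.

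In a self-test of the miR-1 comparison, changes were planted in 200 of 19938 genes. Of these, 84% were recovered at a log2 change of 0.5 and 100% at a log2 change of 1, with 5 unchanged genes called and 0 called in the wrong direction. A further set of genes was given a smaller shift for the list test, and these genes were left out of the count of unchanged genes called. The overlap between microRNAs was set against 20 simulated sets of unchanged groups that shared the control values. Medians of the myotube difference were set against 10000 random lists matched on mean expression, and the range given is the central 95%. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.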

Results

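Gene expression was measured in C2C12 cells, a mouse myoblast line that proliferates in rich medium and fuses into myotubes when serum is withdrawn. The cells received a synthetic mimic of 1 of 7 microRNAs (Let-7b, miR-1, miR-22, miR-29a, miR-34a, miR-145 or miR-365), or the oligonucleotide AllStar as negative control. Each microRNA had 3 arrays, each from its own transfection. The control had 6 arrays, which were 3 transfections and a technical repeat of each, and entered the comparisons as 3 values. Untransfected myoblasts and myotubes had 1 array each, so nothing about these cells was replicated. The 29 arrays held log2 values from 2.35 to 14.65, and the median of an array lay between 7.24 and 7.39. The number of arrays limits the precision. Errors of single genes are standard errors of the model. Errors of gene lists are standard deviations over the 3 samples of the microRNA. They leave out the spread of the 3 control values and so understate the error of a difference. Over the control values the standard deviation was 0.029 for replication, 0.022 for mitosis, 0.092 for sarcomere and 0.12 for cholesterol synthesis genes. Every single gene given below for a microRNA as one of its largest changes had all 3 values on 1 side of all 3 control values. No fold is given where the lower value of such a gene lay under 6.66, the median of the probe sets without a listed gene, because background may set that value. This level was chosen after the values had been seen.

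The first question was whether each mimic lowered genes that are known as targets of its own microRNA. Under miR-29a, collagen genes from its target list fell: Col1a1 by log2 −1.43 ± 0.16, Col3a1 by −1.27 ± 0.15 and Col5a2 by −1.05 ± 0.12. Under miR-34a the cell cycle genes Ccnd1 and Cdk6 fell by −1.36 ± 0.15 and −1.35 ± 0.08, Cdk6 falling under all 7 mimics, and the growth factor receptor gene Met by −1.11 ± 0.09. Under miR-1 the actin regulator Twf1 fell by −1.51 ± 0.11, the receptor gene Notch3 by −1.31 ± 0.21 and the gap junction gene Gja1 by −1.13 ± 0.10. Under Let-7b the Ras gene Nras fell by −1.35 ± 0.12 and Dicer1, which matures microRNAs, by −0.88 ± 0.10. Under miR-365 the metalloproteinase inhibitor Timp3 fell by −1.34 ± 0.23 and the survival gene Bcl2 by −1.03 ± 0.10. Under miR-145 the actin bundling gene Fscn1 fell by −1.41 ± 0.10, and under miR-22 the transcription regulator Purb fell by −0.78 ± 0.18.

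The list of a microRNA's own targets was lower under that microRNA for 7 of 7, and its mean lay below the mean of the same list under each of the other 6. For some lists this margin lay within or near the spread of the samples. The targets of miR-22 were at −0.14 ± 0.03 under miR-22 and −0.11 ± 0.04 under miR-29a. The targets of miR-365 were at −0.32 ± 0.08 under miR-365 and −0.28 ± 0.08 under miR-1. The targets of miR-145 were at −0.11 ± 0.06 under miR-145 and −0.05 ± 0.04 under miR-365, a margin about as large as the spread. For miR-29a 32 of 52 measured members fell (35 adjusted over the list alone), with a mean of −0.45 ± 0.11 (adjusted p = 1.1e-29). For miR-34a 22 of 46 fell (24 adjusted over the list alone) and 3 rose, with a mean of −0.33 ± 0.06 (adjusted p = 1.6e-14). For Let-7b 16 of 50 fell (19 adjusted over the list alone) and 1 rose, with a mean of −0.26 ± 0.05 (adjusted p = 4.6e-09). These 3 calls held with an estimated correlation, with adjusted p = 0.0032 for miR-29a, 0.0311 for miR-34a and 0.0125 for Let-7b. For miR-1 23 of 42 members fell (26 adjusted over the list alone) and 5 rose, with a mean of −0.33 ± 0.09 (adjusted p = 2.1e-08), and adjusted p = 0.0607 with an estimated correlation. For miR-365 9 of 21 fell (10 adjusted over the list alone) and 2 rose, with a mean of −0.32 ± 0.08 (adjusted p = 8.7e-05), and adjusted p = 0.062 with an estimated correlation. For miR-22 7 of 31 fell (8 adjusted over the list alone), with a mean of −0.14 ± 0.03 (adjusted p = 0.0025), and adjusted p = 0.103 with an estimated correlation. For miR-145 13 of 48 fell (18 adjusted over the list alone) and 3 rose (8 adjusted over the list alone), with a mean of −0.11 ± 0.06 (adjusted p = 6.0e-06), and adjusted p = 0.112 with an estimated correlation. Against the mean of the other 6 microRNAs, which uses no control array, the own list was lower in all 7 comparisons, from adjusted p = 2.5e-30 for miR-29a to 0.0074 for miR-22. With an estimated correlation this held for miR-29a (adjusted p = 0.0028) and miR-34a (0.0409), and the other 5 had adjusted p from 0.101 for miR-1 to 0.312 for miR-145. The targets of miR-365 were lower under miR-1 too (mean −0.28 ± 0.08, adjusted p = 0.00049, and adjusted p = 0.103 with an estimated correlation), 11 of 21 members falling and 1 rising (13 and 1 adjusted over the list alone). Some genes stand in several lists, among them Cdk6.

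**Figure D1:**
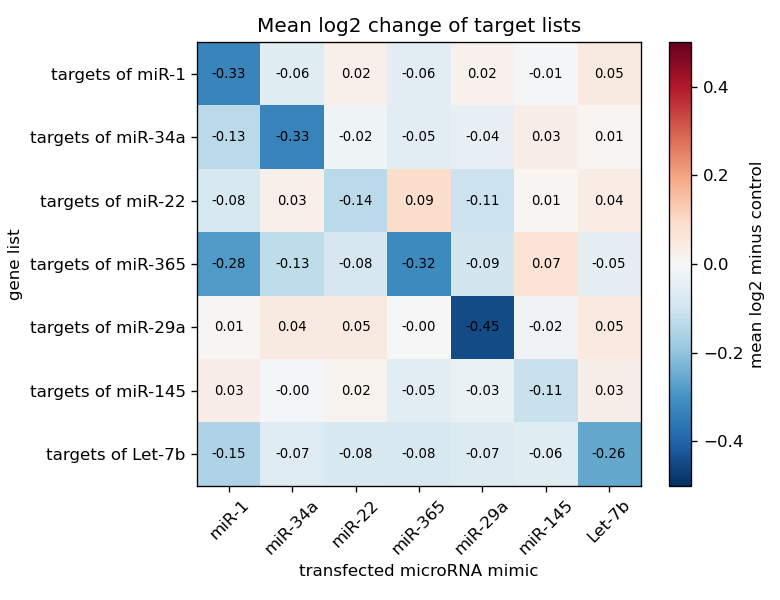
Mean log2 change against control of the 7 target lists (vertical axis) under each of the 7 microRNA mimics (horizontal axis), with blue for lower and red for higher. The lowest mean of each list is on the diagonal, where the list meets its own microRNA, from −0.45 for miR-29a to −0.11 for miR-145.

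The comparison of miR-1, a microRNA abundant in heart and skeletal muscle, with the control asked which genes changed when dividing myoblasts received it. Of the genes of DNA replication 48 of 49 fell, of mitosis genes 50 of 50 fell, and of sarcomere genes 38 of 53 rose, with adjusted p = 0.109, 0.152 and 0.384 for these lists with an estimated correlation. Chek1, a kinase of the DNA damage checkpoint, fell 4.54-fold (log2 −2.18 ± 0.14, adjusted p = 1.3e-09), the chromatin remodeller Hells 3.52-fold and the transcription factor gene E2f5 3.09-fold. Grk6, a kinase that acts on G protein-coupled receptors, the ephrin receptor gene Epha3 and Mboat1 fell between 3.05-fold and 3.20-fold. Neto2 and Fbxo48 fell by log2 −1.92 ± 0.17 to 6.29 and −1.70 ± 0.15 to 6.12. The chemokine receptor gene Cxcr6 rose 6.77-fold, the cell junction gene F11r 4.12-fold and Tinagl1 3.89-fold. From dim control values of 6.39 and 5.79, Hpgd, which inactivates prostaglandins, rose by log2 3.56 ± 0.30 (adjusted p = 1.8e-08) and Usp17la by 2.57 ± 0.26. Usp17la belongs to a family of near-identical genes that a probe set may not separate.

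Under miR-1, 48 of 49 measured genes of DNA replication and S phase fell (48 adjusted over the list alone), with a mean of −1.06 ± 0.27 (adjusted p = 1.8e-46, and adjusted p = 0.109 with an estimated correlation). Examples were the helicase subunit gene Mcm3 at −1.55 ± 0.12, Uhrf1, which recruits DNA methyltransferase, at −1.44 ± 0.15, and the DNA repair gene Brca1 at −1.43 ± 0.14. All 50 measured genes of G2 and mitosis fell (50 adjusted over the list alone), with a mean of −0.91 ± 0.24 (adjusted p = 3.7e-43, and adjusted p = 0.152 with an estimated correlation), among them the transcription factor gene Foxm1 at −1.20 ± 0.14. G1 cyclins, kinases and E2Fs fell in 13 of 20 (15 adjusted over the list alone), with a mean of −0.52 ± 0.09 (adjusted p = 1.9e-10, and adjusted p = 0.0607 with an estimated correlation). Sarcomere genes rose in 38 of 53 (41 adjusted over the list alone), with a mean of 0.72 ± 0.29 (adjusted p = 1.2e-15, and adjusted p = 0.384 with an estimated correlation). The myosin gene Myh1 rose by 1.51 ± 0.31, the thin filament gene Neb by 1.49 ± 0.18 and the calcium pump gene Atp2a1 by 1.46 ± 0.19. Myogenic factors and fusion genes rose in 13 of 28 (15 adjusted over the list alone) and 1 fell, with Myog, a transcription factor of muscle differentiation, 2.14-fold higher (list adjusted p = 7.5e-06, and adjusted p = 0.191 with an estimated correlation). Inhibitors of myogenesis fell in 11 of 22 (11 adjusted over the list alone) and 2 rose, with Snai2 at −1.12 ± 0.14 and Id3 at −1.05 ± 0.11 (list adjusted p = 0.0011, and adjusted p = 0.351 with an estimated correlation), their list mean going from −0.30 to −0.20 without miR-1 replicate 3. Targets of p53 rose in 19 of 27 (20 adjusted over the list alone) and 2 fell, among them Plk3 at 1.28 ± 0.20 (list adjusted p = 1.2e-06, and adjusted p = 0.17 with an estimated correlation).

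Smaller shifts under miR-1 were a rise of glycolysis and hypoxia genes (12 of 26 members, 15 adjusted over the list alone, with 2 lower, mean 0.25 ± 0.10, adjusted p = 0.0006), with the mitophagy receptor gene Bnip3 at 1.04 ± 0.12, and a fall of the Notch pathway (7 of 17, 7 adjusted over the list alone, with 2 higher, mean −0.30 ± 0.16, adjusted p = 0.0241), with Lfng at −1.14 ± 0.15. These 2 lists had adjusted p = 0.17 and adjusted p = 0.435 with an estimated correlation. The Notch list had adjusted p = 0.131 without control replicate 1, 0.0791 without the lowest 40% of genes and 0.0797 without listed targets of miR-1. Means of 0.13 for the unfolded protein and integrated stress response, 0.09 for oxidative phosphorylation, −0.14 for cholesterol synthesis, −0.14 for actin cytoskeleton genes and −0.13 for the targets of miR-34a passed with adjusted p between 0.018 and 0.0311, and had adjusted p from 0.587 to 0.858 with an estimated correlation. All 5 calls ended without the lowest 40% of genes, with adjusted p = 0.109 for the stress response, 0.0791 for oxidative phosphorylation, 0.0795 for cholesterol synthesis, 0.0522 for actin cytoskeleton genes and 0.0795 for the targets of miR-34a. The targets of miR-34a also lost their call with the replicate number as a block (adjusted p = 0.0639), with only miR-1 and the control in the model (0.0683) and without listed targets of miR-1 (0.123), which ended the call for actin cytoskeleton genes too (0.319). Without the technical repeats the adjusted p was 0.0923 for the stress response and 0.0644 for oxidative phosphorylation. With technical pairs as a random block it was 0.0555 for the stress response, 0.0631 for oxidative phosphorylation and 0.0882 for cholesterol synthesis, and it was 0.0975 for the stress response after a further quantile normalization. Each of these 5 calls ended when 1 library was left out, with adjusted p = 0.129 for the stress response without miR-1 replicate 3, 0.0795 without control replicate 1 and 0.0752 without miR-1 replicate 1. It was 0.141 for oxidative phosphorylation, 0.163 for actin cytoskeleton genes and 0.216 for the targets of miR-34a without control replicate 1, and 0.184 for the targets of miR-34a without miR-1 replicate 2. For cholesterol synthesis, lower in 2 of 3 samples, it was 0.2 without control replicate 3, 0.212 without miR-1 replicate 2 and 0.0666 without miR-1 replicate 3. In total 4723 of 19938 genes changed under miR-1, 2627 higher and 2096 lower, and 677 of the higher and 741 of the lower ones by at least 1.5-fold. Of 33 interferon genes 0 passed under miR-1 by limma, with 0 at an unadjusted p under 0.05, and the list mean was −0.13 ± 0.05 (adjusted p = 0.627). This does not show that these genes were unchanged. The model pools the spread of all groups, and under miR-145 the standard deviation of this list was 1.47. The miR-1 samples had list means of −0.15, −0.07 and −0.16, and the lowest control value was −0.04.

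**Figure D2:**
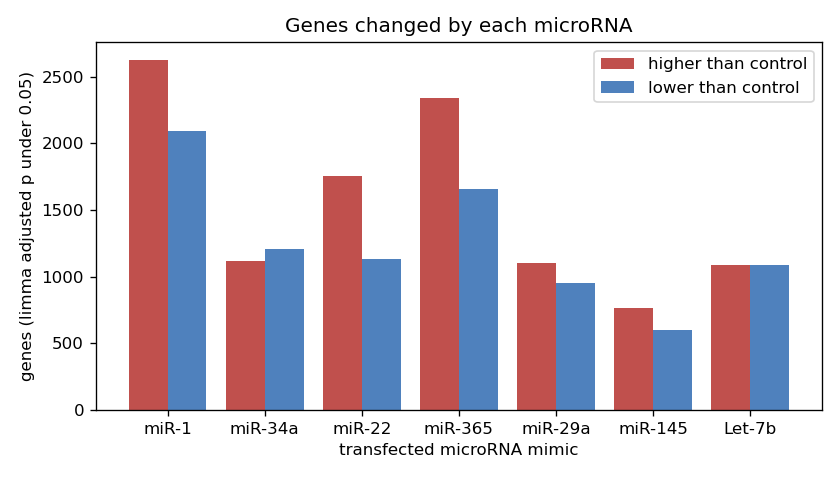
Number of genes (vertical axis) called higher (red) or lower (blue) than control at an adjusted p under 0.05 by limma, for each microRNA mimic (horizontal axis). miR-1 has the most, with 2627 higher and 2096 lower, and miR-145 the fewest, with 767 and 598.

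The comparison of miR-34a, a microRNA induced by p53, with the control asked the same. Of the genes of DNA replication 36 of 49 fell and of sarcomere genes 22 of 53 rose, with adjusted p = 0.241 and 0.38 for these lists with an estimated correlation. Psat1, an enzyme of serine synthesis, fell 3.12-fold (log2 −1.64 ± 0.11, adjusted p = 6.8e-10), Gprc5a 3.08-fold, the translation repressor gene Eif4ebp2 2.88-fold, and Suz12, a subunit of the Polycomb repressive complex, 2.82-fold. Ei24, Mrpl16, Anp32e and the cyclin gene Ccnd1 fell between 2.57-fold and 2.70-fold. The connexin gene Gja5 rose 4.17-fold (log2 2.06 ± 0.17, adjusted p = 3.3e-08), the growth factor gene Fgf7 3.29-fold, Lgr6 3.14-fold, the serotonin receptor gene Htr2b 2.88-fold and the imprinted gene Zim1 2.85-fold.

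DNA replication genes fell under miR-34a in 36 of 49 (40 adjusted over the list alone), with a mean of −0.46 ± 0.03 (adjusted p = 1.7e-25, and adjusted p = 0.241 with an estimated correlation), and Mcm5, a subunit of the replicative helicase, at −1.31 ± 0.21. Mitosis genes fell in 20 of 50 (37 adjusted over the list alone), with a mean of −0.34 ± 0.08 (adjusted p = 2.3e-18, and adjusted p = 0.384 with an estimated correlation). G1 genes fell in 10 of 20 (10 adjusted over the list alone) and 1 rose (mean −0.40 ± 0.05, adjusted p = 1.9e-10, and adjusted p = 0.0607 with an estimated correlation). Sarcomere genes rose in 22 of 53 (33 adjusted over the list alone), with a mean of 0.55 ± 0.04 (adjusted p = 7.4e-17, and adjusted p = 0.38 with an estimated correlation), among them Klhl41 at 1.18 ± 0.24 and the cardiac actin gene Actc1 at 1.00 ± 0.16. Myogenic genes rose in 11 of 28 (17 adjusted over the list alone) and 1 fell, with Myog at 1.12 ± 0.28 (list adjusted p = 2.4e-06, and adjusted p = 0.174 with an estimated correlation). Ribosome biogenesis genes fell in 6 of 28 (13 adjusted over the list alone), with a mean of −0.22 ± 0.06 (adjusted p = 3.2e-09, and adjusted p = 0.342 with an estimated correlation). Glycolysis and hypoxia genes rose in 8 of 26 (10 adjusted over the list alone), with Pdk1, an inhibitor of pyruvate oxidation, at 0.95 ± 0.18 (list adjusted p = 0.0043, and adjusted p = 0.235 with an estimated correlation). In total 2330 genes changed under miR-34a, 1121 higher and 1209 lower, and 268 and 266 of them by at least 1.5-fold. The count was 1523 without control replicate 3 and 1482 without miR-34a replicate 3. With the replicate number as a block in the model it was 3385.

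Under miR-22, 32 of 49 genes of DNA replication fell and 20 of 53 sarcomere genes rose against the control, with adjusted p = 0.311 and 0.492 for these lists with an estimated correlation. Serpinb9, an inhibitor of granzyme B, fell 4.47-fold (log2 −2.16 ± 0.19, adjusted p = 4.4e-08), Ankrd52 2.57-fold, Ankrd13a 2.56-fold, and the chromatin gene Hmgb2 2.49-fold. Cdkn2aipnl, the kinase gene Mast2, Sae1, part of the SUMO activating enzyme, and Hif1an, which hydroxylates hypoxia-inducible factor, fell between 2.32-fold and 2.43-fold. Aspn, a proteoglycan of the extracellular matrix, rose 7.45-fold (log2 2.90 ± 0.43, adjusted p = 5.6e-05), Pi15 6.09-fold, Nptx1 4.13-fold and the muscle stress gene Ankrd2 3.17-fold. Slc16a4 rose by log2 2.51 ± 0.17 from a dim control value of 5.94.

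DNA replication genes fell under miR-22 in 32 of 49 (41 adjusted over the list alone), with a mean of −0.45 ± 0.13 (adjusted p = 9.4e-22, and adjusted p = 0.311 with an estimated correlation), and Slbp, which binds histone mRNA, at −0.96 ± 0.10. Mitosis genes fell in 24 of 50 (32 adjusted over the list alone), with a mean of −0.35 ± 0.16 (adjusted p = 3.0e-15, and adjusted p = 0.458 with an estimated correlation). G1 genes fell in 7 of 20 (10 adjusted over the list alone), with the cyclin gene Ccne1 at −1.16 ± 0.11 (list adjusted p = 3.4e-05, and adjusted p = 0.191 with an estimated correlation). Sarcomere genes rose in 20 of 53 (33 adjusted over the list alone), with a mean of 0.49 ± 0.12 (adjusted p = 5.9e-12, and adjusted p = 0.492 with an estimated correlation), and the myoglobin gene Mb at 1.37 ± 0.28. Targets of p53 rose in 11 of 27 (11 adjusted over the list alone) and 1 fell, with Btg2 at 1.02 ± 0.12 (list adjusted p = 9.4e-05, and adjusted p = 0.264 with an estimated correlation). Unfolded protein and stress response genes rose in 11 of 27 (12 adjusted over the list alone), with Ddit3 at 0.71 ± 0.14 (list adjusted p = 8.2e-05, and adjusted p = 0.219 with an estimated correlation). Myogenic genes rose in 6 of 28 (7 adjusted over the list alone) and 1 fell, with the fusion gene Mymx at 0.95 ± 0.18 (list adjusted p = 0.0074, and adjusted p = 0.497 with an estimated correlation). That list had adjusted p = 0.052 without control replicate 3 and 0.0583 without the lowest 40% of genes. Glycolysis and hypoxia genes rose in 4 of 26 (8 adjusted over the list alone; mean 0.16 ± 0.01, adjusted p = 0.0032, and adjusted p = 0.219 with an estimated correlation), and had adjusted p = 0.0612 without the lowest 40% of genes. Ribosome biogenesis genes fell in 5 of 28 (5 adjusted over the list alone; mean −0.11 ± 0.02, adjusted p = 0.011, and adjusted p = 0.845 with an estimated correlation). In total 2890 genes changed under miR-22, 1759 higher and 1131 lower, and 389 and 231 of them by at least 1.5-fold. The count was 1681 without miR-22 replicate 3 and 4018 with the replicate number as a block.

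Under miR-365, 18 of 20 genes of cholesterol synthesis and 37 of 49 genes of DNA replication fell against the control, with adjusted p = 0.174 and 0.342 for these lists with an estimated correlation. The transcription factor gene Nfib fell 4.34-fold (log2 −2.12 ± 0.19, adjusted p = 4.0e-08), Golm2 3.96-fold, Rp2 3.70-fold and Suclg2, an enzyme of the citric acid cycle, 3.58-fold. Ammecr1, Rell1 and 2610507B11Rik fell between 3.36-fold and 3.60-fold, and Neto2 by log2 −2.06 ± 0.17 to a dim 6.15. 1700007K13Rik rose 7.50-fold (log2 2.91 ± 0.27, adjusted p = 4.5e-08), the chemokine gene Cxcl13 5.23-fold, Igfbp3, which binds insulin-like growth factors, 3.76-fold and the thiamine transporter gene Slc19a2 3.52-fold. Slc16a4 rose by log2 1.87 ± 0.17 from 5.94.

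Cholesterol synthesis genes fell under miR-365 in 18 of 20 (18 adjusted over the list alone), with a mean of −0.65 ± 0.09 (adjusted p = 1.1e-15, and adjusted p = 0.174 with an estimated correlation). The sterol enzyme genes Sc5d, Nsdhl and Cyp51 fell by −1.45 ± 0.09, −1.38 ± 0.10 and −1.27 ± 0.14. The list was lower than under the other 6 microRNAs by −0.62 (adjusted p = 8.1e-14, and adjusted p = 0.269 with an estimated correlation). DNA replication genes fell in 37 of 49 (44 adjusted over the list alone), with a mean of −0.49 ± 0.14 (adjusted p = 4.1e-20, and adjusted p = 0.342 with an estimated correlation), and Cdc6, which loads the replicative helicase, at −1.10 ± 0.16. Mitosis genes fell in 41 of 50 (44 adjusted over the list alone), with a mean of −0.45 ± 0.19 (adjusted p = 3.6e-19, and adjusted p = 0.384 with an estimated correlation), and the kinase gene Nek2 at −1.26 ± 0.14. G1 genes fell in 13 of 20 (13 adjusted over the list alone) and 1 rose, with Skp2, which directs degradation of a kinase inhibitor, at −1.01 ± 0.08 (list adjusted p = 3.0e-07, and adjusted p = 0.112 with an estimated correlation). Targets of p53 rose in 13 of 27 (16 adjusted over the list alone) and 2 fell (4 adjusted over the list alone), with Eda2r at 1.47 ± 0.13 (list adjusted p = 4.3e-06, and adjusted p = 0.174 with an estimated correlation). Actin cytoskeleton genes fell in 15 of 33 (19 adjusted over the list alone) and 1 rose, with the smooth muscle gene Cnn1 at −0.79 ± 0.12 (list adjusted p = 3.4e-07, and adjusted p = 0.38 with an estimated correlation). Glycolysis and hypoxia genes fell in 7 of 26 (7 adjusted over the list alone) and 1 rose, with Ndrg1 at −0.64 ± 0.14 (list adjusted p = 0.0068, and adjusted p = 0.264 with an estimated correlation). Matrix genes fell in 13 of 50 (15 adjusted over the list alone) and 4 rose (5 adjusted over the list alone), with Thbs2 at −1.60 ± 0.12 (list adjusted p = 0.0124, and adjusted p = 0.748 with an estimated correlation). The matrix list had adjusted p = 0.148 without control replicate 1 and 0.0662 without miR-365 replicate 3. In total 3998 genes changed under miR-365, 2338 higher and 1660 lower, and 5131 with the replicate number as a block. Among the larger changes decreases were more frequent, with 382 higher and 550 lower by at least 1.5-fold, and 60 higher and 131 lower by at least 2-fold.

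Under miR-29a, 21 of 50 genes of collagens and the extracellular matrix fell against the control and 2 rose, with adjusted p = 0.174 for this list with an estimated correlation. C1qtnf6, a secreted protein with a collagen-like part, fell 3.83-fold (log2 −1.94 ± 0.14, adjusted p = 8.9e-09), Sh3pxd2a, a scaffold of invasive cell protrusions, 2.72-fold, Ankrd52 2.70-fold, Col1a1 2.70-fold and Cdk6 2.69-fold. The amino acid transporter gene Slc7a1, Col3a1 and Gxylt2 fell between 2.36-fold and 2.54-fold. The serotonin receptor gene Htr2b rose 3.70-fold (log2 1.89 ± 0.15, adjusted p = 2.3e-08), Map3k7cl 2.96-fold, the chemokine gene Ccl9 2.89-fold and the fatty acid binding gene Fabp7 2.65-fold. Aspn rose 2.96-fold (adjusted p = 0.0196), with adjusted p = 0.0554 and 0.0731 without control replicate 1 or 3, and 0.0506 and 0.126 without miR-29a replicate 1 or 2.

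Matrix genes fell under miR-29a in 21 of 50 (22 adjusted over the list alone) and 2 rose (3 adjusted over the list alone), with a mean of −0.29 ± 0.12 (adjusted p = 1.5e-10, and adjusted p = 0.174 with an estimated correlation), and the call ended when the members that are also listed targets of miR-29a were left out (adjusted p = 0.43). Unfolded protein and stress response genes fell in 11 of 27 (14 adjusted over the list alone), with a mean of −0.24 ± 0.05 (adjusted p = 6.6e-10, and adjusted p = 0.0614 with an estimated correlation). Those that moved most were Trib3 at −0.91 ± 0.12 and Chac1 at −0.76 ± 0.13, both induced by the transcription factor ATF4, and Asns at −0.50 ± 0.08, an enzyme of asparagine synthesis. Against the other 6 microRNAs the stress response list was lower by −0.30, and the call held (adjusted p = 1.6e-15, and adjusted p = 0.025 with an estimated correlation). DNA replication genes fell in 2 of 49 (2 adjusted over the list alone), Cdca7 at −0.62 ± 0.12 and Chaf1a at −0.30 ± 0.09, with a list mean of −0.12 ± 0.09 (adjusted p = 0.00085, and adjusted p = 0.861 with an estimated correlation), which was −0.067 (adjusted p = 0.0265) without miR-29a replicate 2. The count of 2 of 49 lay near the share of all genes that fell under miR-29a, 954 of 19938. The mitosis list had a mean of −0.01 ± 0.05 and did not pass (adjusted p = 0.612), and its mean was 0.014 without miR-29a replicate 1. G1 genes fell in 6 of 20 (7 adjusted over the list alone) and 1 rose, with Skp2 at −0.98 ± 0.08 (list adjusted p = 1.2e-05, and adjusted p = 0.174 with an estimated correlation). Sarcomere genes rose in 12 of 53 (16 adjusted over the list alone), with a mean of 0.27 ± 0.22 (adjusted p = 1.2e-05, and adjusted p = 0.786 with an estimated correlation). Myogenic genes rose in 6 of 28 (8 adjusted over the list alone) and 1 fell, with the receptor kinase gene Musk at 0.67 ± 0.17 (list adjusted p = 0.0143, and adjusted p = 0.56 with an estimated correlation). The myogenic list had adjusted p = 0.127 without control replicate 3 and 0.0806 without miR-29a replicate 2. Ribosome biogenesis genes fell in 3 of 28 (3 adjusted over the list alone; mean −0.10 ± 0.11, lower in 2 of 3 samples, adjusted p = 0.0058, and adjusted p = 0.801 with an estimated correlation), and had adjusted p = 0.254 without miR-29a replicate 2. In total 2058 genes changed under miR-29a, 1104 higher and 954 lower, and 200 and 232 of them by at least 1.5-fold. The count was 1330 without control replicate 3, 1337 without miR-29a replicate 3, and 3142 with the replicate number as a block.

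Under miR-145, 18 of 33 interferon response genes rose against the control, most of all in replicate 3, with adjusted p = 0.384 for this list with an estimated correlation. Ifit3, an antiviral gene induced by interferon, rose by log2 4.50 ± 0.61 (adjusted p = 5.3e-05) from a dim control value of 5.32, Usp18, which removes the ubiquitin-like protein ISG15, by 3.43 ± 0.65 from 6.52, and Rtp4 by 2.54 ± 0.49 from 6.20. Ifit1 rose 11.1-fold and the chemokine gene Cxcl10 9.83-fold. Ifit3 has a close copy that its probe set may not separate. Of the 33 measured interferon genes 18 rose (30 adjusted over the list alone), with a mean of 1.51 ± 1.47 (adjusted p = 1.0e-18, and adjusted p = 0.384 with an estimated correlation). The list mean of replicates 1, 2 and 3 stood at 0.73, 0.59 and 3.21 above the control mean, and the other 21 values lay between −0.16 and 0.31. Without miR-145 replicate 3 the list mean was 0.66 (adjusted p = 5.3e-26), Ifit3 was at 3.11, Ifit1 at 2.21, Usp18 at 1.93, Cxcl10 at 2.14 and Rtp4 at 1.40. Against the other 6 microRNAs the list was higher by 1.44 (adjusted p = 1.1e-15, and adjusted p = 0.474 with an estimated correlation). Immune cell markers had a mean of 0.03 ± 0.06 under miR-145 and did not pass (adjusted p = 0.857).

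**Figure D3:**
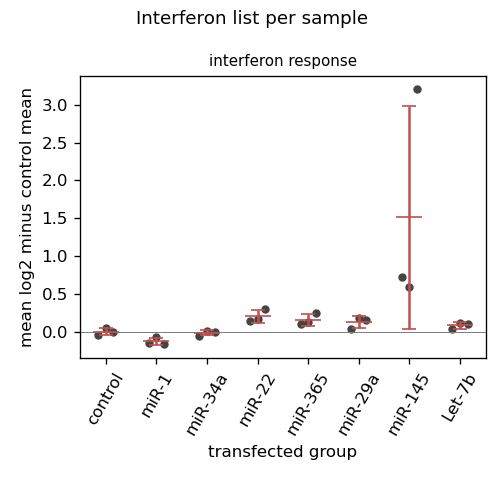
Mean log2 value of the 33 interferon response genes in each sample, minus the control mean (vertical axis), by transfected group (horizontal axis). Points are samples, bars the mean and standard deviation of 3. The miR-145 samples stand at 0.73, 0.59 and 3.21, and the other 21 values between −0.16 and 0.31.

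The largest decreases under miR-145 were in Gsta4, a glutathione transferase, at 4.10-fold (log2 −2.03 ± 0.31, adjusted p = 0.00017), the iron exporter gene Slc40a1 at 3.67-fold, Car8 at 3.24-fold and Nqo1, a quinone reductase, at 3.03-fold. Prrg4, Musk, a receptor kinase of the neuromuscular junction, and Anxa8 fell between 2.68-fold and 2.71-fold. Prl2c5, which has near-identical copies, fell 2.91-fold (adjusted p = 0.022), with adjusted p = 0.109 and 0.0607 without control replicate 1 or 2, and 0.0859 and 0.119 without miR-145 replicate 2 or 3. DNA replication genes had a mean of −0.13 ± 0.10 (adjusted p = 3.4e-06, and adjusted p = 0.786 with an estimated correlation), Uhrf1 falling by −0.64 ± 0.15 and Pcna, the sliding clamp of DNA polymerase, by −0.17 ± 0.05, while Rfc5 rose by 0.39 ± 0.11 (2 lower and 1 higher adjusted over the list alone). Of all 19938 genes 598 fell and 767 rose under miR-145. Mitosis genes had a mean of −0.08 ± 0.06 (adjusted p = 0.00063, and adjusted p = 0.87 with an estimated correlation), which was −0.044 (adjusted p = 0.0328) without miR-145 replicate 3, although 0 of 50 passed singly by limma, 0 adjusted over the list alone and 5 were lower at an unadjusted p under 0.05. Sarcomere genes rose in 7 of 53 (8 adjusted over the list alone), with the titin gene Ttn at 1.06 ± 0.23. That list mean was 0.23 ± 0.28 and higher in 2 of 3 samples (adjusted p = 0.0064, and adjusted p = 0.926 with an estimated correlation). The sarcomere list had a mean of 0.19 (adjusted p = 0.0566) without control replicate 3, 0.14 (0.526) without miR-145 replicate 2 and 0.15 (0.0717) without miR-145 replicate 3. G1 genes fell in 4 of 20 and 1 rose (4 and 1 adjusted over the list alone; adjusted p = 0.0138, and adjusted p = 0.492 with an estimated correlation), Cdk6 at −0.67 ± 0.08 among them, and that list had adjusted p = 0.109 without the lowest 40% of genes and 0.458 without listed targets of miR-145.

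Means of −0.13 for inhibitors of myogenesis, 0.14 for glycolysis and hypoxia genes, −0.10 for the microRNA machinery and −0.06 for the targets of Let-7b also passed under miR-145, with adjusted p of 0.0036, 0.0296, 0.0199 and 0.0253, and had adjusted p = 0.393, 0.384, 0.422 and 0.311 with an estimated correlation. Members that fell were Id2 at −0.47 ± 0.08 in the list of inhibitors and Ago3, an Argonaute gene, at −0.53 ± 0.09 in the microRNA machinery. At an unadjusted p under 0.05 by limma, 7 inhibitors of 22 were lower and 1 higher, and 5 genes of 13 in the microRNA machinery were lower and 1 higher. Without miR-145 replicate 3 the means were −0.056 for the inhibitors, 0.12 for glycolysis and −0.074 for the microRNA machinery. The adjusted p was then 0.0732, 0.0697 and 0.0619 in that order. Without miR-145 replicate 2 it was 0.138 for glycolysis, and without control replicate 1 it was 0.131 for the microRNA machinery and 0.114 for the targets of Let-7b. It was 0.11 for the microRNA machinery and 0.0848 for the targets of Let-7b without the lowest 40% of genes, and 0.118 for glycolysis without the technical repeats. Without listed targets of miR-145 it was 0.0559 for glycolysis and 0.0723 for the targets of Let-7b. In total 1365 genes changed under miR-145, 767 higher and 598 lower, 162 and 144 of them by at least 1.5-fold, and 2444 with the replicate number as a block. The count was 727 without miR-145 replicate 3, whose interferon genes stood highest, 824 without control replicate 2 and 756 without control replicate 3. The count was 654 with only miR-145 and the control in the model, where Ifit1, Usp18, Cxcl10 and Rtp4 had adjusted p of 0.0592, 0.109, 0.0666 and 0.115.

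Under Let-7b, 12 of 27 stress response genes rose and 6 of 53 sarcomere genes fell against the control. With an estimated correlation these lists had adjusted p = 0.154 and 0.833, and without Let-7b replicate 1 the sarcomere list had adjusted p = 0.22. The protease-like gene Capn6 fell 3.97-fold (log2 −1.99 ± 0.12, adjusted p = 1.1e-09), the peptide hormone gene Edn1 2.71-fold, Tarbp2, a partner of Dicer, 2.61-fold, the growth factor gene Pdgfb 2.61-fold and Nras 2.55-fold. Tmem198b, Cmas, an enzyme of sialic acid activation, and the chloride transporter gene Clcn5 fell between 2.39-fold and 2.50-fold. Pi15 rose 5.21-fold (log2 2.38 ± 0.20, adjusted p = 4.1e-08), the leukocyte surface gene Cd53 4.56-fold and Aldh3a1 3.59-fold. From dim control values of 5.74 and 6.26, the proton pump subunit gene Atp6v0d2 rose by log2 2.27 ± 0.30 and the phosphatase gene Ptpn22 by 1.83 ± 0.24. Immune cell markers had a mean of 0.10 ± 0.06 under Let-7b and did not pass (adjusted p = 0.457).

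Unfolded protein and stress response genes rose under Let-7b in 12 of 27 (15 adjusted over the list alone) and 1 fell, with the transcription factor gene Atf3 2.14-fold higher, the cystine transporter gene Slc7a11 at 1.06 ± 0.17 and Ddit3 at 0.87 ± 0.14 (list adjusted p = 2.2e-06, and adjusted p = 0.154 with an estimated correlation). Sarcomere genes fell in 6 of 53 (9 adjusted over the list alone), with Actc1 at −1.13 ± 0.16 and the skeletal actin gene Acta1 at −0.80 ± 0.15. Their mean was −0.24 ± 0.28, lower in 2 of 3 samples (adjusted p = 5.2e-05, and adjusted p = 0.833 with an estimated correlation), and it was −0.09 (adjusted p = 0.22) without Let-7b replicate 1. Against the other 6 microRNAs the sarcomere list was lower by −0.63 (adjusted p = 1.2e-22, and adjusted p = 0.312 with an estimated correlation). Of the myogenic genes Myod1, which starts muscle commitment, fell by −0.55 ± 0.14 and Myf5 by −0.34 ± 0.10, 2 of 28 (5 adjusted over the list alone), while Mef2a rose (list adjusted p = 0.0228, and adjusted p = 0.587 with an estimated correlation). Under Let-7b 1089 of all 19938 genes fell. Without control replicate 1 or 2, or Let-7b replicate 1, the myogenic list had adjusted p of 0.14, 0.0537 and 0.475, and it had 0.0548 after a further quantile normalization and 0.149 without the lowest 40% of genes. Actin cytoskeleton genes fell in 8 of 33 (9 adjusted over the list alone), with the transcription factor gene Srf at −0.86 ± 0.13 (list adjusted p = 5.8e-05, and adjusted p = 0.515 with an estimated correlation). In the microRNA machinery 4 of 13 fell (6 adjusted over the list alone) and 2 rose, Dicer1 at −0.88 ± 0.10 and Ago2 at −0.50 ± 0.07 among them (list adjusted p = 0.0122, and adjusted p = 0.384 with an estimated correlation), and that list had adjusted p = 0.0899 without control replicate 1, 0.0523 with only Let-7b and the control in the model and 0.104 without listed targets of Let-7b.

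DNA replication genes fell under Let-7b in 3 of 49 (2 adjusted over the list alone), with a mean of −0.17 ± 0.10 (adjusted p = 4.7e-05, and adjusted p = 0.849 with an estimated correlation). Mitosis genes fell in 3 of 50 (3 adjusted over the list alone), with the survivin gene Birc5 at −1.13 ± 0.15 and a list mean of −0.10 ± 0.03 (adjusted p = 0.0372, and adjusted p = 0.987 with an estimated correlation). The member counts of both lists lay near the share of all genes that fell under Let-7b, 1089 of 19938. The mitosis list had adjusted p = 0.0649 without control replicate 3, and 0.0972 and 0.0988 without Let-7b replicate 1 or 3. It had 0.064 with the technical repeats as the only controls, 0.125 after a further quantile normalization, 0.19 without the lowest 40% of genes and 0.104 without listed targets of Let-7b. G1 genes fell in 7 of 20 (8 adjusted over the list alone) and 1 rose, with E2f2 at −0.98 ± 0.15 (list adjusted p = 3.5e-05, adjusted p = 0.191 with an estimated correlation and 0.139 without listed targets of Let-7b). Ribosome biogenesis genes fell in 4 of 28 (13 adjusted over the list alone), with Rrp12 at −0.51 ± 0.10 (list adjusted p = 2.2e-06, and adjusted p = 0.458 with an estimated correlation). Oxidative phosphorylation genes had a mean of −0.07 with 3 of 30 lower (5 adjusted over the list alone; adjusted p = 0.0044, adjusted p = 0.515 with an estimated correlation and 0.0694 after a further quantile normalization). Notch pathway genes fell in 4 of 17 (5 adjusted over the list alone), with the protease gene Adam10 at −0.75 ± 0.10, while the ligand gene Jag1 rose by 0.77 ± 0.17 (list adjusted p = 0.0241, and adjusted p = 0.435 with an estimated correlation). The Notch list had adjusted p = 0.196 without control replicate 1, 0.0668 and 0.0681 without Let-7b replicate 1 or 3, and 0.109 without the lowest 40% of genes. In total 2176 genes changed under Let-7b, 1087 higher and 1089 lower, and 261 and 221 of them by at least 1.5-fold. The count was 1380 without Let-7b replicate 3 and 3299 with the replicate number as a block.

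Across the 7 microRNAs, the replication list separated miR-1, miR-34a, miR-22 and miR-365, with means from −1.06 to −0.45, from miR-29a, miR-145 and Let-7b, with means from −0.17 to −0.12. Against the mean of the other 6 microRNAs, replication genes were lower under miR-1 by −0.76 (adjusted p = 4.4e-33), and higher under miR-29a by 0.34 (adjusted p = 3.2e-17), under miR-145 by 0.33 (adjusted p = 3.6e-13) and under Let-7b by 0.28 (adjusted p = 3.6e-13). With an estimated correlation these 4 calls had adjusted p = 0.269, 0.453, 0.474 and 0.474. For miR-34a, miR-22 and miR-365 this difference did not pass (adjusted p of 0.331, 0.413 and 0.115). Sarcomere genes were higher than under the other microRNAs for miR-1 by 0.49, miR-34a by 0.29 and miR-22 by 0.23 (adjusted p of 3.6e-11, 1.0e-07 and 0.00024, and adjusted p of 0.486, 0.615 and 0.767 with an estimated correlation). They were lower than under the other microRNAs for Let-7b by −0.63 (adjusted p = 1.2e-22, and adjusted p = 0.312 with an estimated correlation), for miR-365 by −0.26 (adjusted p = 0.00094, and adjusted p = 0.809 with an estimated correlation) and for miR-145 by −0.09 (adjusted p = 0.0369, and adjusted p = 0.877 with an estimated correlation), although the list was higher under miR-145 than in the control. For miR-29a the difference was −0.03 and did not pass (adjusted p = 0.838). Against the control the sarcomere list was not lower under miR-365, with a mean of 0.08 ± 0.09 that did not pass by camera (adjusted p = 0.55), 4 of 53 members rising and 4 falling. Of all 19938 genes 2338 rose and 1660 fell under miR-365. Of 231 pairs of a list and a microRNA, 73 passed against the control, 52 lower and 21 higher, and 3 passed with an estimated correlation. The mean, the median and the test had 1 sign in each of the 73, and 69 of them had 3 of 3 samples in that direction.

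**Figure D4:**
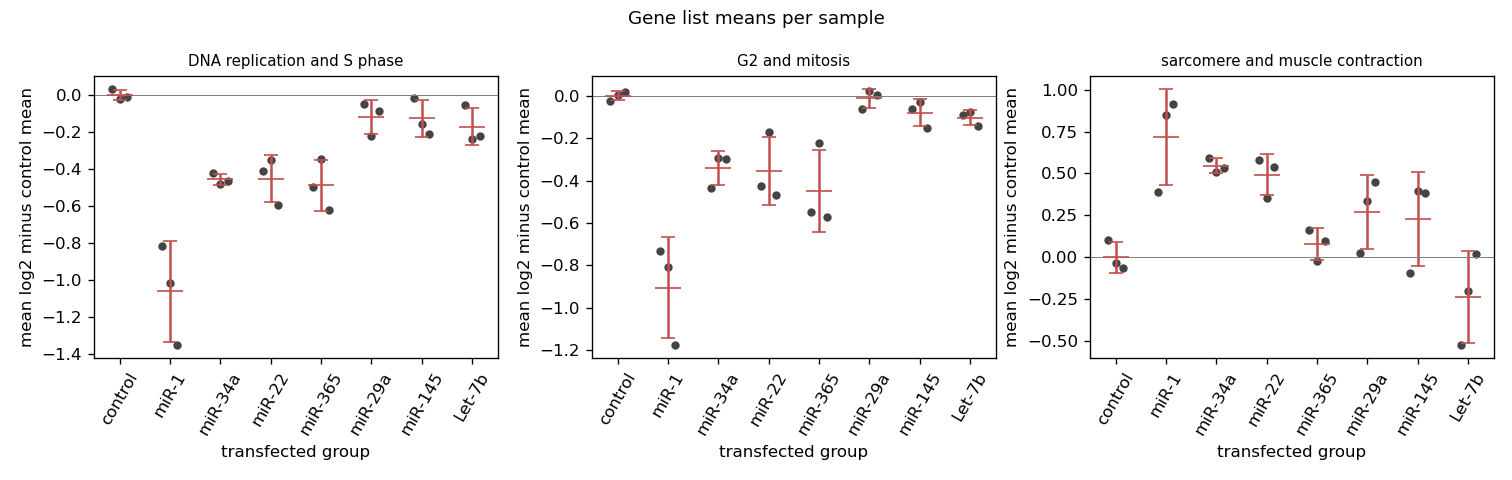
Mean log2 value per sample, minus the control mean (vertical axes), of DNA replication, mitosis and sarcomere genes by transfected group (horizontal axes). Points are samples, bars the mean and standard deviation of 3. miR-1 is lowest for replication at a mean of −1.06 and for mitosis at −0.91, and highest for the sarcomere at 0.72, where Let-7b is at −0.24.

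Several gene groups did not pass as lists under any of the 7 microRNAs. This does not mean that their members were unchanged, since members that move both ways cancel in a list mean. Cyclin-dependent kinase inhibitors and pocket proteins had list means from −0.27 under miR-1 to 0.03 under Let-7b, with a smallest adjusted p of 0.184. Of the 9 measured members 3 fell and 1 rose under miR-1, and over the 7 microRNAs members passed 19 times. Genes of the pentose phosphate pathway ran from −0.07 to 0.17 (smallest adjusted p = 0.0937), and genes of apoptosis and survival from −0.08 to 0.09 (smallest adjusted p = 0.174). Counted over the 7 microRNAs and both directions, single members passed 11 times for the 7 measured pentose phosphate genes and 31 times for the 20 genes of apoptosis. Markers of adipocytes, osteoblasts, immune cells, endothelial cells, neurons and glia, and epithelia made 42 pairs with the microRNAs, with means from −0.17 to 0.26. The smallest adjusted p among the marker lists was 0.181, for adipocyte markers under miR-34a, with a mean of 0.21.

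Genes were also compared across microRNAs. Cdk6, a kinase that drives entry into S phase, Grk6, the acetyltransferase gene Naa40, the nuclear pore gene Ndc1 and Tlcd3a fell under all 7 microRNAs, with mean changes from −0.90 for Cdk6 to −0.51 for Tlcd3a. A dimmer probe set of Tlcd3a had the opposite sign under miR-22, miR-365 and miR-145. The histone genes H3c15 and H2ac4, which have near-identical copies, the cyclin gene Ccnf, Kcnk5 and Itpripl1 fell under 6. Under all 7 microRNAs 31 genes rose, with Prxl2a at a mean of 1.20, the phosphatase gene Acp1 at 1.18, Hoatz at 1.11 and Scarna13, a small RNA of Cajal bodies, at 0.97. Hoatz rose from a dim control value of 6.45, which background may set. Slc25a36, Dusp3, Dnajc24, the exoribonuclease gene Xrn1, Mxra8 and the sarcoglycan gene Sgcb rose between 0.62 and 0.79 on average. In at least 4 microRNAs 358 genes fell, where independent calls would give 8.16, and 648 rose, where they would give 17.6. Simulated unchanged groups that shared the controls gave 0 genes in at least 4, but only 0.35 lower and 0.5 higher genes in any group by the same limma model, so this value does not measure what shared control error adds to real changes. miR-1 and miR-34a lowered 581 genes in common, against 127 from the product of their counts over all genes, and raised 600, against 148. The covariance of their log2 changes was 0.0305, where simulated groups sharing the controls gave 0.0062. For miR-365 and miR-145 it was 0.0073 against 0.0062 simulated. Part of the excess may come from the 3 control values that all comparisons share, which cannot be split into independent sets.

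Over all 8 transfected groups 9850 of 19938 genes differed by limma's F test. Against the mean of the other 6 microRNAs, 5733 genes differed for miR-1, 5391 for miR-365, 3758 for miR-145, 3682 for Let-7b, 3400 for miR-29a, 3148 for miR-22 and 2807 for miR-34a.

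The untransfected arrays asked how differentiated cells differ from myoblasts, and whether the genes changed by a microRNA differ the same way. The median of the sarcomere list was higher in myotubes than in myoblasts by 1.17 and that of the replication list lower by −1.08. Fmod, a proteoglycan that binds collagen, was 13.8-fold lower, Id3, an inhibitor of myogenic transcription factors, 8.53-fold and the Wnt binding gene Sfrp2 8.49-fold. Slc7a11, Gprin3 and Slc1a3 were between 7.70-fold and 8.21-fold lower, and the histone genes H1f5, H2ac15, H2bc3 and H4c6, which have near-identical copies, between 7.27-fold and 10.6-fold. The acetylcholinesterase gene Ache was 7.37-fold higher in myotubes, and Lce1h, Prrg4, Perp and Mcpt8 between 7.64-fold and 11.6-fold. Other genes were dim in 1 of the 2 cell states. Of these Aspn and Fabp7 were lower in myotubes by log2 −4.05 and −3.27. Higher were 1700007K13Rik by log2 4.84, the mast cell protease gene Mcpt1 by 4.10, Dnase1l3 by 3.58, Ces2g by 3.46, Gzme by 3.19, Crct1 by 3.08 and Ppp1r3a, which targets a phosphatase to glycogen, by 2.95. At least 2-fold differences were seen for 540 genes higher and 400 lower. The median difference was 1.17 for the sarcomere list, 0.48 for myogenic genes, 0.52 for p53 targets, 0.32 for oxidative phosphorylation, −1.08 for replication genes, −0.97 for mitosis genes, −0.54 for cholesterol synthesis and −0.46 for inhibitors of myogenesis, each outside the central range of 10000 random lists of like expression. With 1 array each, no test on samples was possible.

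Genes lowered by miR-1 had a median myotube difference of −0.33 (random lists 0.00 to 0.04), and 77.5% of them were lower in myotubes. Without the 98 of these 2096 genes that are in the replication or mitosis list the median was −0.30. Genes raised by miR-1 had a median of 0.31 (random lists 0.01 to 0.05). For miR-34a the medians were −0.18 and 0.26, for miR-22 −0.16 and 0.23, for miR-365 −0.20 and 0.18, and for miR-29a −0.06 and 0.18, each outside its random range. Genes lowered by Let-7b had a median of 0.03 and genes lowered by miR-145 one of 0.01, both inside their random ranges, while genes raised by Let-7b and by miR-145 had medians of 0.12, above theirs. Across all genes, the change under miR-1 had a Pearson's r of 0.461 and a Spearman's rho of 0.408 with the myotube difference, the largest of 7 such correlations. The smallest r was 0.0616, for Let-7b. Against the mean of the other microRNAs, which uses no control, r was 0.383 for miR-1, 0.084 for miR-365 and 0.041 for miR-22. It was −0.032 for miR-34a, −0.180 for miR-29a, −0.186 for miR-145 and −0.234 for Let-7b. That comparison only sets the microRNAs against each other. For microRNAs other than miR-1, it therefore stays open whether the shared control values made the likeness to myotubes. All these correlations are across genes, and genes are not independent replicates.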

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

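All tests in this part were chosen after the results they weigh had been seen.

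Of the 12146 probe sets without a listed gene, which no comparison used, 1254 (10.3%) differed among the 8 groups by limma's F test, and against the control alone 456 changed under miR-1 and 65 under miR-145. Of the 1621 probe sets with several gene symbols, 450 (27.8%) passed the F test, and against the control 252 changed under miR-1 and 16 under miR-145. Both were listed here whatever their counts, because they lie outside the main measurement. Of the 19938 genes tested 9850 passed the F test, a larger share than in either set. The 33 lists were also examined for a control array standing apart from the other 5, and 0 did, where chance would give about 1.65.

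The 36 genes that changed the same way under all 7 microRNAs, 31 higher and 5 lower, included Cdk6, Acp1 and Prxl2a. Chance error in the 3 shared control values stays open, since the simulated unchanged groups, with 0 genes in at least 4 of 7, had hardly any calls and decide nothing. An effect of the control oligonucleotide itself is a candidate explanation, since the untransfected myoblast lay on the microRNA side of the control for 32 of the 36, with a median of 0.46 (random genes −0.13 to 0.06), and 0.40 and 0.57 for the higher and lower genes. A response to every mimic may add to it, since the microRNA means lay beyond the myoblast by a median of 0.13, just over the random range of −0.06 to 0.12, but the medians of the higher genes (0.13) and the lower genes (−0.06) taken separately lay inside their ranges. These medians were computed on 3 sets of genes and rest on 1 myoblast array, which would also lie on the microRNA side if the control values alone were in error.

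Interferon genes under miR-145 stood highest in replicate 3. That replicate 3 alone carries the rise is argued against by the other miR-145 samples, the lower of which had a list mean of 0.59, above the highest of the 21 other values at 0.31. Immune cells in replicate 3 are argued against by the immune marker mean of 0.054 in that sample, inside the −0.06 to 0.17 of the other values, with Lyz2 at 0.17, Tyrobp at 0.06, Laptm5 at 0.12 and Cd68 at −0.44 against the control. A difference in how replicate 3 was transfected, and a response of the cells to this mimic, stay open and were not tested.

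Other groupings of the samples were counted for each number of changed genes. For each microRNA against the control, the 6 values allow 10 splits into 3 and 3, too few for a share under 0.05. In 1 of the 10 splits, the real one, the count was reached, with 4723 genes for miR-1, 2330 for miR-34a, 2890 for miR-22, 3998 for miR-365, 2058 for miR-29a, 1365 for miR-145 and 2176 for Let-7b, and the highest count of any other split was 0 by limma, with up to 4083 genes at an unadjusted p under 0.05. For the F test 1 of 100 groupings of the 24 values, made without regard to replicate number, reached 9850 genes, the real one, and the highest of the others was 76. With values exchanged only within a replicate number, again 1 of 100 reached it and the highest of the others was 1087. That all 8 groups are alike is therefore unlikely, although 1 of 100 is the smallest share that these groupings can give. This does not decide the count of any single microRNA.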

How the results depend on the processing

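The values without miR-145 replicate 3 for the other microRNAs were chosen after seeing the data, and all other alternatives here were planned. No called result reversed. The mitosis list under miR-29a, which did not pass, had a mean of −0.012 that turned to 0.0025 after a further quantile normalization and ran from −0.029 to 0.014 with 1 library left out (0.014 without miR-29a replicate 1), and Zmat3 under miR-1, which did not pass, ran from −0.013 without miR-1 replicate 3 to 0.163 without miR-1 replicate 2. Over the alternatives, counts of changed genes moved by more than 1.5 times in 13, and calls of the target, replication and mitosis lists were lost in 24. Counting each pair of a result and an alternative once, the other lists that passed kept their side of the threshold in 879 and lost it in 121, and single named genes kept it in 10880, gained it in 534 and lost it in 367. The cause was not tested except where fewer samples or genes remain. With the replicate number as a block, 3142 genes changed under miR-29a, 2444 under miR-145 and 3299 under Let-7b, and the targets of miR-34a under miR-1 lost their call (adjusted p = 0.0639). With only miR-145 and the control in the model 654 changed. Leaving out 1 library gave 1482 to 2482 genes for miR-34a, 1681 to 3090 for miR-22, 1330 to 2236 for miR-29a, 727 to 1410 for miR-145 and 1380 to 2322 for Let-7b. The mitosis list under Let-7b had means of −0.12 to −0.084 with 1 library left out, −0.10 (adjusted p = 0.064) with the technical repeats as the only controls, −0.087 (0.125) after a further quantile normalization, −0.10 (0.19) without the lowest 40% of genes and −0.095 (0.104) without targets of Let-7b, and over all its alternatives the adjusted p ran from 0.0028 to 0.987.

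With the correlation estimated for each list the means are unchanged by construction, and these calls were lost. For replication the means were −1.06 for miR-1, −0.46 for miR-34a, −0.45 for miR-22, −0.49 for miR-365, −0.12 for miR-29a, −0.13 for miR-145 and −0.17 for Let-7b. For mitosis they were −0.91 for miR-1, −0.34 for miR-34a, −0.35 for miR-22, −0.45 for miR-365, −0.080 for miR-145 and −0.10 for Let-7b. For own targets they were −0.33 for miR-1, −0.14 for miR-22, −0.32 for miR-365 and −0.11 for miR-145.

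The median myotube difference at an adjusted p under 0.01 was −0.39 for genes lowered and 0.35 for genes raised by miR-1, 0.28 for genes raised by miR-22 and 0.21 for genes raised by miR-365. Without the replication and mitosis lists it was −0.30 for genes lowered by miR-1, −0.15 by miR-34a, −0.13 by miR-22 and −0.17 by miR-365. The alternative with all 6 control arrays treated each technical pair as a random block (correlation 0.607) and tested lists on the moderated statistics. Where 2 arrays were left in a group, its spread was pooled with the other groups. The seed site test and its alternatives were not run. Dim genes limit the signal over background, which was not measured separately.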

Other observations

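The correlation without controls was chosen as a test after the values of the myotube pattern had been seen, and the median without the replication and mitosis lists, planned beforehand, was read as a test of the pattern only then.

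Control cells and untransfected myoblasts had a Pearson's r of 0.990 across genes, and 57 genes were at least 2-fold higher and 242 at least 2-fold lower in the control mean than on the myoblast array. With 1 myoblast array this difference was not tested.

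Genes lowered by miR-1 were lower in myotubes and genes raised by it higher. The shared control samples are argued against by the comparison of miR-1 with the other 6 microRNAs, which uses no control and had an r of 0.383 across genes with the myotube difference. Taken singly against the 6 others r ran from 0.211 to 0.401, and for single miR-1 samples against all 6 from 0.279 to 0.441. Cell cycle genes as the source of the lower values stay open, because the median without the replication and mitosis lists (−0.30) rests on taking out only 98 of 2096 genes, too few to bring it to the random lists. Whether miR-1 moved the cells toward the myotube profile is left open, since 1 myotube array and 1 myoblast array cannot test it.

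Genes whose 3 microRNA values lay wholly to 1 side of the 3 control values numbered 6836 (34.3%) for miR-1, 5687 (28.5%) for miR-34a, 6148 (30.8%) for miR-22, 6834 (34.3%) for miR-365, 5180 (26.0%) for miR-29a, 4707 (23.6%) for miR-145 and 5511 (27.6%) for Let-7b, where chance gives 10% for 3 against 3. The lowest count of changed genes with 1 library left out came without the microRNA's own replicate 3 in each comparison, except for miR-29a, where it came without control replicate 3 (1330, against 1337 without its own replicate 3).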
